A study of Homo sapiens with 4 samples.

How the data were processed

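Polyadenylated RNA was sequenced in 4 libraries, 2 labelled as MRG15 knockdown by a lentiviral shRNA (shMRG) and 2 as vector control. The authors ran FastQC and then kallisto, which assigns reads to annotated transcripts of the human genome build GRCh38 without aligning them base by base. The versions of both tools and the release of the transcript set are not given in the sources used here. Per the file headers, each deposited table lists 188753 transcripts with a length and an effective length in bases, an estimated count and a TPM. The deposited expected counts (kallisto's estimated counts) are reads assigned to each transcript, not normalized and not whole numbers. The deposited TPM values are counts per effective length, scaled to the same sum in each library. The deposited lengths and effective lengths are the remaining (other) unit and served as an offset in 1 alternative.

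Transcripts were matched to genes of GENCODE 29 by transcript identifier without its version. This matched 169754 transcripts (89.9%) of 35544 genes, and 93.6% of the matched transcripts had the annotated length. Unmatched transcripts, which held between 1.72% and 1.84% of the counts, were left out of the gene tests. Symbols were found for 756 of 759 list genes. Totals per library were 18354311, 20599086, 20378342 and 20164207 estimated counts for shMRG replicates 1 and 2 and control replicates 1 and 2. A count of 0 was read as allowing up to 3 counts, and this limit covers counting error only. Isoforms share reads, and the assignment error of the estimated counts was not available.

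Estimated counts were summed per gene and rounded. The gene test was edgeR's quasi-likelihood F test (glmQLFit and glmQLFTest, edgeR 4.0.16, limma 3.58.1, R 4.3.3), two-sided, with TMM normalization, group as the only term and the genes kept by filterByExpr with its minimum count of 10 and minimum total of 15. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. The common dispersion was 0.0184, the residual degrees of freedom were 2, the prior degrees of freedom were 6.15 and normalization factors lay between 0.944 and 1.05. The SE of a log2 fold change came from the same fit, and CPM were TMM-normalized. The correlation of log2 CPM was 0.984 between the controls and 0.978 between the shMRG libraries. Between a control and a shMRG library it lay between 0.965 and 0.976. The shMRG libraries were thus hardly closer to each other than shMRG replicate 1 was to the controls. These correlations run across genes, and genes are not independent replicates.

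Gene lists with at least 5 tested members were tested with camera at a preset correlation of 0.01 on log2 CPM with a prior count of 2, adjusted over 29 lists, and again with camera's estimated correlation and with fry. The 32 lists covered senescence and the cell cycle (CDK inhibitors, senescence secretory factors, genes lowered in senescent cells, G1/S and G2/M), partners of MRG15 and H3K36 methylation, DNA repair, interferon and NF-kB targets, stress responses, metabolism, mitochondria, ribosomes, histones, lysosomes, immediate early genes, matrix, RNA granules, splicing, telomeres and markers of neurons, fibroblasts, blood, liver and epithelium. Members called over all genes and when adjusted over the list alone were counted. Transcript usage was tested with edgeR's diffSpliceDGE on transcripts with at least 10 counts in at least 2 libraries, by the F test per gene.

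The groups, tests, lists, alternatives and the rule for named genes were chosen before the data were examined. The rule took MORF4L1 and MORF4L2, the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 CPM and groups that did not overlap, and 12 senescence genes whatever their result, of which 2 are not reported here, nor is 1 of the lists. It also took the 3 members with the lowest adjusted p of each list with called members, and, for usage, the 6 genes with the lowest adjusted p together with FGFR2, TPM1, TPM2 and PKM. Other genes of a list are named where its called members are listed.

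The alternatives were DESeq2 1.42.0, DESeq2 size factors or library totals in edgeR, no filter, a mean of at least 5 CPM, an offset for effective length, limma voom, limma on log2(TPM + 1) with a mean TPM of at least 1, the same with 0.1 added or without a filter, protein-coding genes only, replicate number as a block, and each library left out in turn. For the count of genes an adjusted p under 0.01 and glmTreat against a fold of 1.2 were added. For usage they were at least 50 counts, at least 10% of the gene's counts and the Simes p. The replicates of a group were treated as independent.

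The tests were checked on simulated data of the same size with 200 changed genes. The gene test recovered 28.6% of genes changed 1.5-fold, 56.3% at 2-fold, 87.2% at 4-fold and 97.9% at 8-fold, and 6.90% of its 145 calls fell on unchanged genes. Camera gave a list shifted 1.41-fold an adjusted p of 5.74e-13 and called 2 of 100 unchanged lists at an unadjusted p under 0.05. Genes were simulated independently of each other, so this does not check the preset correlation for lists whose genes vary together. The correlation estimated for the G1/S list was 0.750. The usage test recovered 74% of 150 tested genes whose 2 main transcripts were switched and differed at least 2-fold. Of its 159 calls, 28.9% fell on genes without a switch. Each transcript's count was drawn on its own, so the simulation holds no error in assigning reads between isoforms. Figures were drawn with matplotlib 3.10.9.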

Results

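RNA abundance was measured by sequencing of polyadenylated RNA in 4 human cell libraries that the labels assign to HEK293T, a transformed line derived from embryonic kidney. A lentivirus carried an shRNA against MRG15 into 2 of them (shMRG), and the other 2 carried the vector (control). MRG15 is the chromodomain protein encoded by MORF4L1, a subunit of histone acetyltransferase and deacetylase complexes that binds methylated lysine 36 of histone H3. The total was 18354311 estimated counts in shMRG replicate 1, 20599086 in shMRG replicate 2, 20378342 in control replicate 1 and 20164207 in control replicate 2. The labels do not state whether the libraries of a group came from separate cultures, so every p measures only the spread between these 4 libraries. The comparison asks how loss of MRG15 changes gene expression related to cellular senescence, the lasting arrest of cell division. All changes are shMRG relative to control, ± gives the SD of 2 libraries per group, and adjusted p values come from edgeR unless another tool is named.

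MORF4L1, the target of the shRNA, fell to 27.0% of its control level. Its level was 250.1 ± 13.8 CPM, the gene's counts scaled to a common library total, in control and 67.5 ± 18.4 CPM in shMRG libraries, a log2 fold change of -1.89 (SE 0.18, adjusted p = 0.00434). The remaining share was 21.8% in shMRG replicate 1 and 32.2% in shMRG replicate 2. MORF4L1 (ENSG00000185787) lies on chromosome 15 between 78810487 and 78898133 of GRCh38. Its transcript MORF4L1-203 held 74.8% of the gene's counts in control libraries and stood at 26.2% of its control level in shMRG. The paralog MORF4L2 (ENSG00000123562, chromosome X) measured 306.2 ± 15.1 CPM in control and 289.3 ± 18.7 CPM in shMRG, a log2 fold change of -0.08 (SE 0.12, adjusted p = 0.762). No processed pseudogene of either gene exceeded 1.04 estimated counts in any library. On log2(TPM + 1) the log2 fold change of MORF4L1 was -1.77 and its limma adjusted p was 0.0635.

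**Figure D1:**
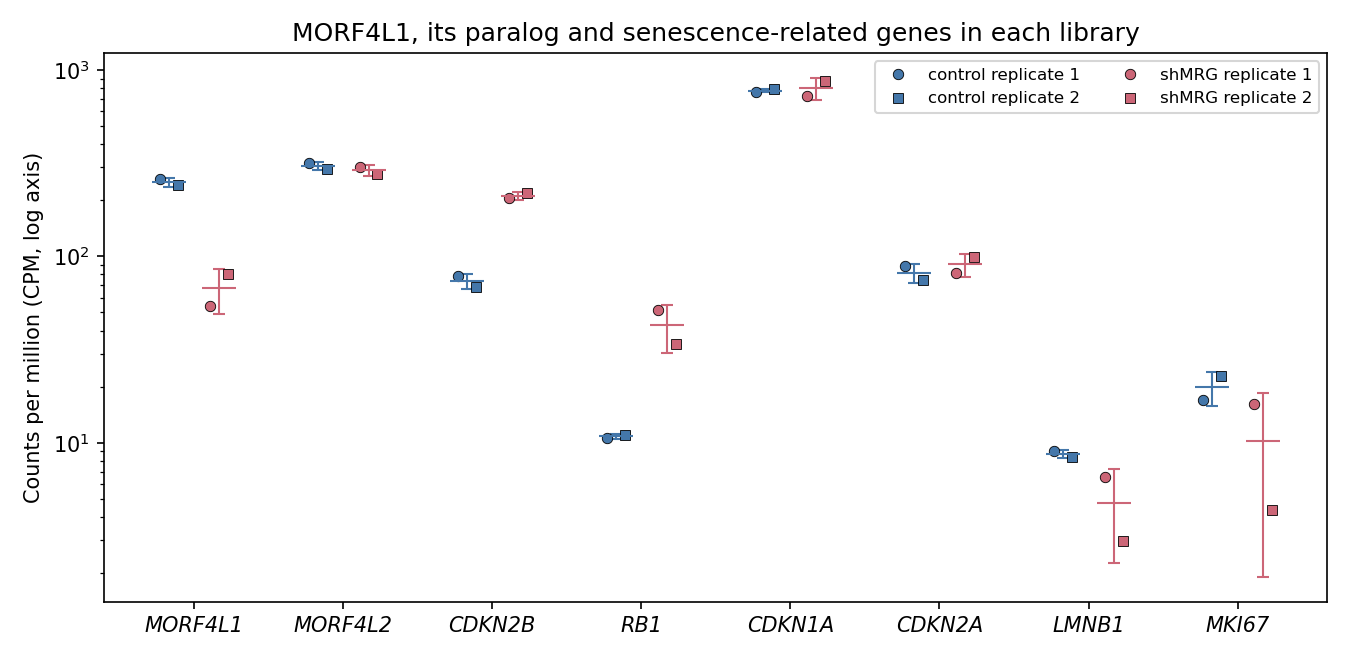
CPM on a logarithmic axis for MORF4L1, its paralog MORF4L2 and 6 senescence and cell cycle genes; points are libraries, bars are group means with SD (n = 2 per group). MORF4L1 falls from 250.1 to 67.5 CPM, CDKN2B and RB1 rise, and CDKN1A has group means of 776.1 and 799.3 CPM.

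Cells with the knockdown gained transcripts of the cell cycle inhibitors CDKN2B and RB1 and lost transcripts of some DNA replication enzymes. Of 42 G1/S and DNA replication genes, 11 fell and 31 did not pass the test. CDKN2B, which encodes the CDK4/6 inhibitor p15, rose 2.87-fold, from 73.6 ± 6.94 to 211.1 ± 9.16 CPM (SE 0.12 on the log2 scale, adjusted p = 0.00324). RB1, the retinoblastoma protein that restrains entry into S phase, rose 3.94-fold, from 10.8 ± 0.306 to 42.7 ± 12.3 CPM (adjusted p = 0.00542). The thymidylate synthase TYMS fell from 24.8 ± 0.0211 to 6.25 ± 2.24 CPM (adjusted p = 0.00857), and the replicative helicase subunit MCM5 fell from 30.7 ± 0.65 to 8.04 ± 3.3 CPM (adjusted p = 0.011). In all, 151 of 13486 tested genes rose and 212 fell.

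Of these 363 genes, 200 changed by at least 1 on the log2 scale, 71 of them upward and 129 downward. All 363 had groups that did not overlap, which was so for 51.2% of all tested genes against 33.3% by chance. Among genes with a mean of at least 5 CPM, the 10 largest rises were those of TAP2, DIO2, RB1, ENC1, TMEM178B, H2BC4, SESN3, H2BC5, EDN1 and ABCA1. DIO2, which converts thyroid hormone to its active form, rose by 2.82 on the log2 scale (SE 0.48, adjusted p = 0.0269). ENC1, an actin-binding protein (ENSG00000171617, chromosome 5, 74627406 to 74641424), rose from 47.1 ± 9.69 to 170.5 ± 4.4 CPM (adjusted p = 0.00348). EDN1, the precursor of the vasoconstrictor endothelin 1, rose from 8.39 ± 2.09 to 26.4 ± 6.57 CPM (adjusted p = 0.0134), and the cholesterol exporter ABCA1 rose from 36.1 ± 3.37 to 111.4 ± 24.6 CPM (adjusted p = 0.00542). TMEM178B, SESN3 and the histone gene H2BC5 rose by 1.85, 1.70 and 1.69 on the log2 scale (adjusted p = 0.0489, 0.0353 and 0.0248). TAP2, a peptide transporter of antigen presentation, rose from 1.38 ± 0.972 to 13.4 ± 2.26 CPM (adjusted p = 0.00941). Together with 12 transcripts of the same lengths that the annotation did not match, it went from 17.2 ± 1.47 to 22.3 ± 8.79 CPM.

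The 10 largest falls were those of TOX, GPM6B, CDCA7, ITGA10, EIF3CL, CRYBG1, HELLS, TYMS, MDK and MCM5. TOX, a high mobility group transcription factor (ENSG00000198846, chromosome 8, 58805418 to 59119208), fell from 9.91 ± 1.32 to 1.21 ± 0.307 CPM, a log2 fold change of -3.03 (SE 0.29, adjusted p = 0.00434). The collagen receptor subunit ITGA10 fell from 18.5 ± 0.752 to 3.61 ± 0.214 CPM (adjusted p = 0.00324), and CRYBG1 fell from 63.9 ± 10.6 to 14.9 ± 2.05 CPM (adjusted p = 0.00324). The growth factor midkine, encoded by MDK, had a log2 fold change of -1.98 (adjusted p = 0.00857), and the membrane glycoprotein GPM6B one of -2.43 (adjusted p = 0.00857). The chromatin remodeller HELLS and its activator CDCA7 had log2 fold changes of -2.02 and -2.41 (adjusted p = 0.0135 and 0.0465). CDCA7 measured 11.1 ± 1.34 CPM in control, 3.39 CPM in shMRG replicate 1 and 0.786 CPM in shMRG replicate 2. EIF3CL fell by 2.23 on the log2 scale (adjusted p = 0.0403), while its near-identical copy EIF3C measured 219.1 CPM in control and 216.7 CPM in shMRG. The counts of both together were 229.7 ± 0.839 CPM in control and 218.9 ± 15.5 CPM in shMRG.

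The number of changed genes was 74 without control replicate 1, 53 without control replicate 2, 2317 without shMRG replicate 1 and 1138 without shMRG replicate 2, and it was 61 with an offset for effective transcript length. With that offset the log2 fold change of RB1 was 1.49 (adjusted p = 0.103), and CDKN2B kept its call (adjusted p = 0.0153). A fit with a library left out has 1 library in its group and takes the spread from the other group. The controls lay closer together than the shMRG libraries (correlations of 0.984 and 0.978), so calls without a shMRG library can be inflated. Counts and p values given below without a library are therefore no tests of their own.

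Replication genes were the senescence-related group with the most members that fell, 11 of 42 G1/S and DNA replication genes, against 2 of 12 genes known to be lowered in senescent cells and 0 of 54 G2/M and mitosis genes. The median log2 fold changes of these lists were -0.92, -0.63 and -0.54, and each list was called lower with camera's preset correlation but not with an estimated one (adjusted p = 0.831, 0.844 and 0.858 with an estimated correlation). CDKN2B was the 1 CDK inhibitor of 7 that rose, and CDKN1A did not pass the test.

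Of the 42 G1/S genes, 11 fell, none rose and 31 did not pass the test (30 lower and 0 higher when adjusted over the list alone; camera adjusted p = 3.66e-16). The correlation between these genes estimated from the libraries was 0.750, and the call was lost with it (adjusted p = 0.831 with an estimated correlation). CDCA7, CHAF1B, GINS2, HELLS, MCM2, MCM4, MCM5, MCM6, NASP, RRM2 and TYMS were the members that fell. The helicase subunits MCM4 and MCM6 had log2 fold changes of -1.34 and -1.21 (adjusted p = 0.00936 and 0.00857). Relative to the control mean, the list's median was -0.58 in shMRG replicate 1 and -1.22 in shMRG replicate 2. The number that fell was 4 without control replicate 1, 4 without control replicate 2, 36 without shMRG replicate 1 and 16 without shMRG replicate 2. It was 3 with the offset for effective length, 0 on log2(TPM + 1) and on log2(TPM + 0.1), and 18 with the replicate number as a block.

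None of the 54 G2/M genes passed the test, over all genes or when adjusted over the list alone, although 48 had negative log2 fold changes and 12 had an unadjusted p under 0.05 (camera adjusted p = 1.26e-06). That call was lost too (adjusted p = 0.858 with an estimated correlation). The list's median relative to the control mean was -0.17 in shMRG replicate 1 and -1.07 in shMRG replicate 2. Without shMRG replicate 1 the list's median log2 fold change was -1.13, and without shMRG replicate 2 it was -0.18. The proliferation marker MKI67 had a log2 fold change of -0.96 (adjusted p = 0.319), and without shMRG replicate 1 it was -2.19.

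All 12 genes lowered in senescent cells had negative log2 fold changes, and 2 of them, HELLS and DNMT1, passed the test over all genes and when adjusted over the list alone (camera adjusted p = 2.63e-04). With the correlation taken from the data the list was not called (adjusted p = 0.844 with an estimated correlation). The maintenance DNA methyltransferase DNMT1 fell by 0.92 on the log2 scale (adjusted p = 0.00936). The nuclear lamina gene LMNB1 had a log2 fold change of -0.87 (adjusted p = 0.217), HMGB1 one of -0.19 (adjusted p = 0.413) and HMGB2 one of -0.48 (adjusted p = 0.507). Without shMRG replicate 1, LMNB1 and HMGB2 had log2 fold changes of -1.54 and -1.24. The list's median was -1.11 without shMRG replicate 1 and -0.29 without shMRG replicate 2. It was -0.85 without control replicate 1 and -0.51 without control replicate 2.

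Of 7 CDK inhibitors, CDKN2B alone rose and none fell (1 higher and 1 lower when adjusted over the list alone; camera adjusted p = 0.973). The number lower was 2 without shMRG replicate 1 and 1 with the replicate number as a block. CDKN1A, which encodes p21, measured 776.1 ± 18 CPM in control and 799.3 ± 108 CPM in shMRG (adjusted p = 0.91). CDKN2A, the gene of p16 and ARF, had a log2 fold change of 0.15 (adjusted p = 0.604).

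Of 30 senescence secretory factors, 3 rose and none fell (5 higher and 2 lower when adjusted over the list alone). These were the urokinase PLAU, with a log2 fold change of 1.48 (adjusted p = 0.0132), the lipase inhibitor ANGPTL4 at 1.25 (adjusted p = 0.0137) and the growth factor FGF2 at 0.68 (adjusted p = 0.0212). The list's median was 0.29 and its camera adjusted p was 0.0511. That p was 0.0210 without control replicate 1 (2 higher), 0.218 without control replicate 2 (0 higher), 0.866 without shMRG replicate 1 (8 higher, 5 lower) and 0.00347 without shMRG replicate 2 (12 higher, 2 lower). The inflammatory factors IL6 and CXCL8 had log2 fold changes of -0.58 and 0.63 (adjusted p = 0.443 and 0.386). GLB1, the gene of the beta-galactosidase used to stain senescent cells, had a log2 fold change of 0.27 (adjusted p = 0.233).

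**Figure D2:**
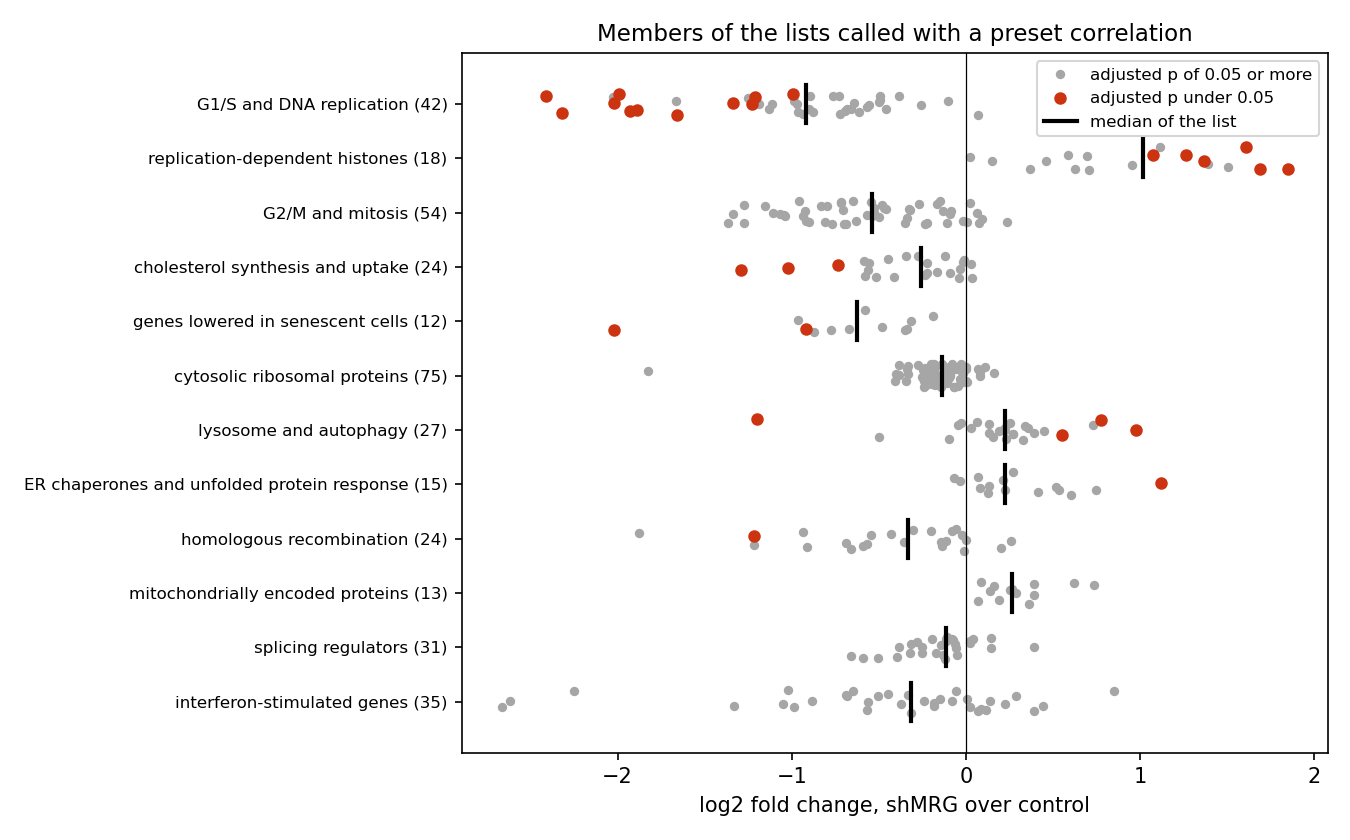
Log2 fold change, shMRG relative to control, of each tested member of the 12 gene lists with a camera adjusted p under 0.05; red points passed the gene test, black bars are medians, and the number tested is in brackets. The G1/S list has a median of -0.92 and the histone list one of 1.01.

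Among the other fixed lists, 6 of 18 replication-dependent histone genes rose and 3 of 24 genes of cholesterol synthesis and uptake fell. The median log2 fold changes were 1.01 and -0.26, and both lists were called with the preset correlation but not with an estimated one (adjusted p = 0.788 and 0.831 with an estimated correlation). Of 15 chaperone and stress genes of the endoplasmic reticulum (ER) 1 rose, of 27 lysosome and autophagy genes 3 rose and 1 fell, and of 24 homologous recombination genes 1 fell. Their medians were 0.23, 0.23 and -0.33, and these calls too were lost with an estimated one (adjusted p = 0.831 for each with an estimated correlation).

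Of the 18 histone genes, 6 rose and none fell (11 higher and 0 lower when adjusted over the list alone; camera adjusted p = 6.32e-10), and the list was not called with the correlation taken from the data (adjusted p = 0.788 with an estimated correlation). The genes that rose were H1-2, H2AC6, H2BC15, H2BC4, H2BC5 and H4C8, whose main transcripts lack a poly(A) tail in dividing cells. H2BC4 rose from 3.78 ± 0.222 to 13.6 ± 0.269 CPM (adjusted p = 0.00542), H1-2 rose by 1.37 (adjusted p = 0.00567) and H2AC6 by 1.08 on the log2 scale (adjusted p = 0.00939). Without control replicate 1 or control replicate 2, the number that rose was 2.

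Of the 24 cholesterol genes, 3 fell and none rose (0 higher and 9 lower when adjusted over the list alone; camera adjusted p = 2.30e-05; adjusted p = 0.831 with an estimated correlation). ACAT2, which makes acetoacetyl-CoA, fell by 1.02 (adjusted p = 0.00562), the sterol-regulated TMEM97 by 1.29 (adjusted p = 0.00939) and INSIG1, a brake on sterol synthesis, by 0.74 on the log2 scale (adjusted p = 0.0465). The number that fell was 1 without control replicate 2, 12 without shMRG replicate 1 and 8 without shMRG replicate 2.

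Of 15 ER chaperone and unfolded protein response genes, 13 had positive log2 fold changes and 1, the co-chaperone DNAJB9, rose, by 1.12 on the log2 scale (adjusted p = 0.0114). When adjusted over the list alone, 6 were higher and 0 lower (camera adjusted p = 0.00118; adjusted p = 0.831 with an estimated correlation). The number that rose was 0 without control replicate 2, 7 without shMRG replicate 1 and 6 without shMRG replicate 2.

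Of 27 lysosome and autophagy genes, the autophagy genes SQSTM1, MAP1LC3B and GABARAPL1 rose and the beta-glucuronidase gene GUSB fell (5 higher and 1 lower when adjusted over the list alone). SQSTM1 rose by 0.98 (adjusted p = 0.015), MAP1LC3B by 0.78 (adjusted p = 0.0353), and GUSB had a log2 fold change of -1.20 (adjusted p = 0.0134). The camera adjusted p of that list was 0.00103, and the call was lost without control replicate 2 (0.0607) and with the correlation taken from the data (adjusted p = 0.831 with an estimated correlation). With either control replicate left out no member passed the test, and 8 were higher with either shMRG replicate left out, with 2 lower without the first and 1 lower without the second.

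Of 24 homologous recombination genes, RAD51D alone fell, by 1.21 on the log2 scale (adjusted p = 0.0132; 0 higher and 3 lower when adjusted over the list alone; camera adjusted p = 0.00183; adjusted p = 0.831 with an estimated correlation). The number that fell was 0 with either control replicate left out, 9 without shMRG replicate 1 (median -0.61) and 2 without shMRG replicate 2.

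None of the 13 mitochondrially encoded proteins, 75 cytosolic ribosomal proteins or 31 splicing regulators passed the gene test, over all genes or when adjusted over the list alone. As groups, the mitochondrial genes were higher with a median log2 fold change of 0.26 (camera adjusted p = 0.0088; adjusted p = 0.858 with an estimated correlation). The ribosomal protein genes were lower with a median of -0.14 (camera adjusted p = 3.68e-04; adjusted p = 0.858 with an estimated correlation). The splicing regulators were lower with a median of -0.11 (camera adjusted p = 0.0107; adjusted p = 0.847 with an estimated correlation). Without control replicate 1 the adjusted p values of these lists were 0.0511, 0.264 and 0.0527. Without shMRG replicate 2 those of the mitochondrial and splicing lists were 0.346 and 0.136, and without shMRG replicate 1 that of the ribosomal list was 0.101. Without shMRG replicate 1, 11 mitochondrial genes were higher, and 5 ribosomal and 8 splicing genes were lower. Without shMRG replicate 2, 1 mitochondrial gene was higher, 6 ribosomal genes were lower, and 1 splicing gene was higher and 2 were lower.

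The interferon-stimulated genes split the shMRG libraries. Relative to the control mean, the median of 35 genes was 0.22 in shMRG replicate 1 and -1.54 in shMRG replicate 2. Over both libraries the median log2 fold change was -0.31 (camera adjusted p = 0.0311; adjusted p = 0.866 with an estimated correlation), and no gene passed the test over all genes or when adjusted over the list alone, while 4 had an unadjusted p under 0.05. Without shMRG replicate 1 the list's direction was lower, and without shMRG replicate 2 it was higher. The camera call was lost at a mean of 5 CPM (0.0519) and on log2(TPM + 0.1) (0.0650).

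Among the partners of MRG15, none of 17 NuA4/TIP60 genes and none of 21 SIN3-HDAC genes passed the test, over all genes or when adjusted over the list alone (camera adjusted p = 0.125 and 0.734). Of the SIN3-HDAC genes, 1 was higher and 1 lower without shMRG replicate 1. Of 19 writers, readers and erasers of H3K36 methylation, the methyltransferase NSD2 and the reader PHF19 fell, by 0.92 and 0.75 on the log2 scale (adjusted p = 0.0128 and 0.0454). The list as a whole was not called (0 higher and 3 lower when adjusted over the list alone; camera adjusted p = 0.480). It had 0 members past the threshold without control replicate 2, and 3 higher and 3 lower without shMRG replicate 1. Of 18 ATF4 targets, the cystine transporter SLC7A11 and the receptor VLDLR rose, by 0.76 and 0.57 (adjusted p = 0.028 and 0.0438), and the serine synthesis enzyme PHGDH fell by 0.53 on the log2 scale (adjusted p = 0.0437). That list had 6 higher and 2 lower when adjusted over the list alone and a camera adjusted p of 0.103, which lay between 0.00811 (without shMRG replicate 2) and 0.491 (without shMRG replicate 1) with a library left out. That p was also under 0.05 with limma voom (0.0489) and on log2(TPM + 1) (0.04998), and no member passed the test with either control replicate left out. Of 17 hypoxia-induced genes, ANGPTL4 rose while the carbonic anhydrase CA12 and the aldolase ALDOC fell, by 1.38 and 1.10 on the log2 scale (adjusted p = 0.00936 and 0.016; 1 higher and 3 lower when adjusted over the list alone; camera adjusted p = 0.721). That list had 1 higher and 1 lower without control replicate 1, none without control replicate 2, 4 higher and 3 lower without shMRG replicate 1, and 1 higher and 4 lower without shMRG replicate 2.

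No member of the NF-kB target, heat shock, AP-1, RNA granule, telomerase and shelterin or nuclear respiratory chain lists passed the test, over all genes or when adjusted over the list alone. Without shMRG replicate 1, 1 NF-kB target was higher and 3 were lower, 3 heat shock genes were higher, 1 AP-1 gene was higher and 4 were lower, and 3 RNA granule genes and 1 respiratory chain gene were lower. Without shMRG replicate 2, 3 AP-1 genes were higher. The camera adjusted p values were 0.216 for 15 NF-kB targets, 0.216 for 10 heat shock genes, 0.833 for 20 AP-1 and immediate early genes, 0.103 for 21 RNA granule and paraspeckle genes, 0.466 for 10 telomerase and shelterin genes and 0.919 for 42 respiratory chain genes. Of 22 matrix and mesenchymal genes, the transcription factor TWIST1 alone fell, by 1.04 on the log2 scale (adjusted p = 0.00724; 2 higher and 3 lower when adjusted over the list alone; camera adjusted p = 0.973). That list had 9 higher and 4 lower without shMRG replicate 1, 1 higher and 6 lower without shMRG replicate 2, and 3 lower with library totals only. Median, mean and test differed in sign for the CDK inhibitors, H3K36, AP-1 and matrix lists.

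With camera's preset correlation, 4 of 29 tested lists were higher and 8 lower. With an estimated correlation camera called 0 lists, the histone list being the 1 with an unadjusted p under 0.05. That test rests on 2 residual degrees of freedom, so a call lost with it need not come from correlation between genes. With fry, which tests whether a list's genes move one way, 0 lists were called (adjusted p of at least 0.157) and 4 had an unadjusted p under 0.05. The fry test rests on the same 2 residual degrees of freedom, so the same limit holds for its lost calls.

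Transcripts typical of fibroblasts were abundant in all 4 libraries, in both groups. All 10 fibroblast markers exceeded 10 TPM, a level scaled for transcript length and library total, in every library, with a median of 417.6 TPM in control and 429.1 TPM in shMRG. COL1A1, a chain of type I collagen, measured 6796 ± 48.2 TPM in control and 5864 ± 1903 TPM in shMRG, and the fibronectin gene FN1 measured 22543 ± 234 and 18170 ± 261 TPM. The 10 markers made up between 1.21% and 1.86% of all transcripts. Of 16 neuronal genes known to be expressed in HEK293 cells, 2 exceeded 10 TPM in all libraries and 6 stayed below 1 TPM in all, with a median of 0.609 TPM in control and 0.766 TPM in shMRG. All 10 blood cell markers stayed below 1 TPM. Liver markers reached at most 4.0 TPM and the 9 listed keratinocyte and epithelial markers at most 5.89 TPM, which does not cover epithelial genes outside that list. TERT, the telomerase reverse transcriptase, was listed at 0 estimated counts in each library, which allows a level of up to 0.163 CPM in the library with the fewest counts (3 counts, counting error only).

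No fibroblast marker passed the test over all genes, and 0 were higher and 1 was lower when adjusted over the list alone (median log2 fold change -0.14, camera adjusted p = 0.734). Without shMRG replicate 2 the list was lower with 5 members lower (adjusted p = 0.0141), and without shMRG replicate 1 it was not called, with 2 higher and 1 lower (adjusted p = 0.232). Of 9 tested neuronal genes, MAP2 rose by 1.07 on the log2 scale (adjusted p = 0.0183) and the neurofilament gene NEFM had a log2 fold change of -1.59 (adjusted p = 0.0495; 2 higher and 1 lower when adjusted over the list alone; camera adjusted p = 0.734). None passed the test with either control replicate left out, and 1 was higher and 3 were lower without shMRG replicate 1.

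**Figure D3:**
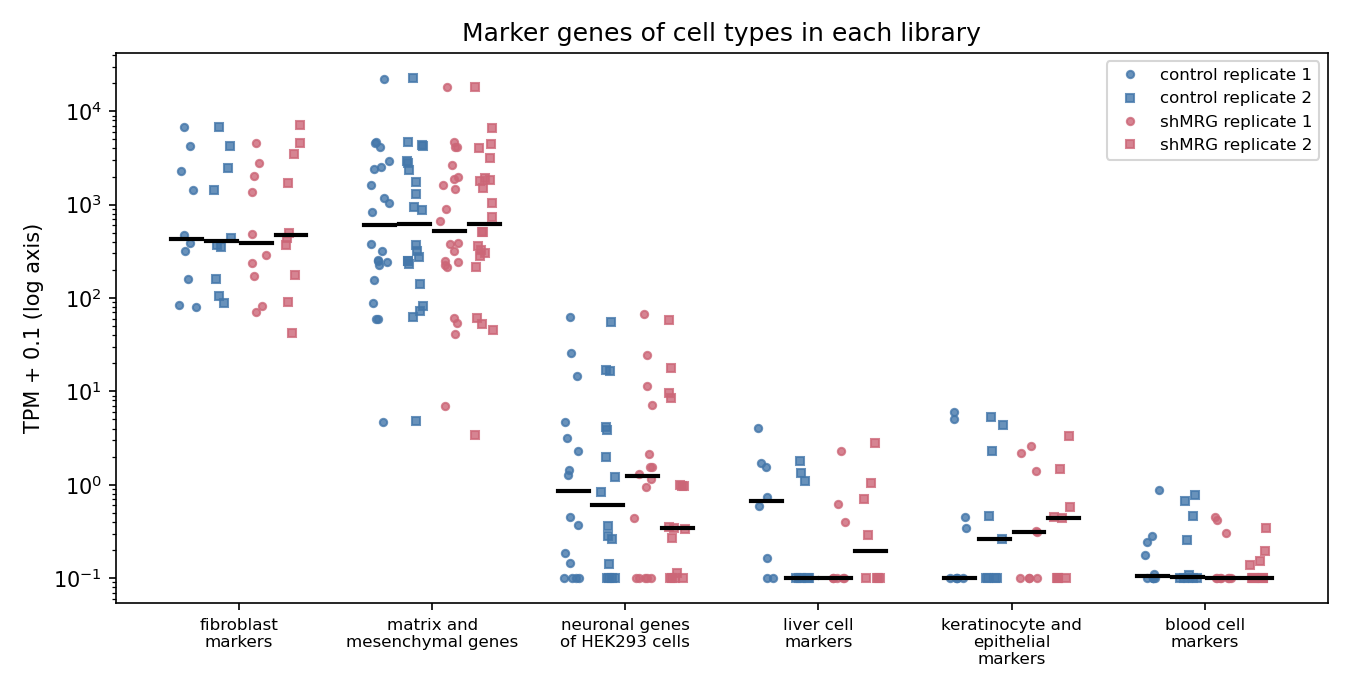
TPM plus 0.1, on a logarithmic axis, of the genes of 6 marker lists in each of the 4 libraries; points are genes and black bars are medians. The fibroblast markers have medians of 417.6 TPM in control and 429.1 TPM in shMRG, and the neuronal genes have medians of 0.609 and 0.766 TPM.

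Within genes, the lowest adjusted p values for a change in the proportions of transcripts were those of TCP1, a chaperonin subunit, XBP1, a transcription factor of the unfolded protein response, and ZNF226, a zinc finger gene. TCP1-203 held 8.89% ± 0.601 of the gene's counts in shMRG and near 0% in control (adjusted p of the gene = 5.09e-05). XBP1-207 had 0 counts in both control libraries, which allows shares of up to 0.108% and 0.114%, and held 13.1% ± 4.39 of the gene in shMRG (adjusted p = 1.42e-04). ZNF226-202 had 0 counts in control (up to 1.10% and 1.51%) and held 27.8% ± 2.23 of the gene in shMRG. ZNF226-215 went from 20.9% ± 4.96 to 0 counts (up to 1.2% and 1.64%), and the adjusted p of the gene was 3.16e-04. The limits for XBP1 and ZNF226 cover counting error only. Error in assigning reads between isoforms of a gene was not available, so the true shares can lie above them.

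ARFGAP1, SLC3A2 and ZSCAN30 followed, with adjusted p values of 8.49e-04, 9.75e-04 and 0.00172. ARFGAP1-212 went from 6.31% to 0.0595% of its gene and ZSCAN30-211 from 31.0% to 6.11%. Usage changed in 119 of 9526 genes tested, 5 of which also changed in total level, where independent lists would share 3.36. In an edgeR test of the level of each single transcript, 0 of 45988 transcripts had an adjusted p under 0.05. That test also missed MORF4L1-203, the main transcript of the shRNA's target. It measured 195 and 179 CPM in the control libraries and 38.6 and 59.5 CPM in the shMRG libraries. The 0 therefore does not show that transcripts were unchanged. The splice targets TPM1, TPM2 and PKM, to which MRG15 has been tied, did not pass the test (adjusted p = 1 for each). For FGFR2, another such target, the 2 tested transcripts had between 0 and 26.35 counts in a library, too few for the test to decide. The transcript PKM-202 held 91.1% ± 0.157 of PKM in control and 90.1% ± 0.0545 in shMRG, TPM1-206 held 58.9% and 61.0% of its gene, and TPM2-204 held 82.1% and 81.9%. The simulated share of false usage calls, given next, leaves out error in assigning reads between isoforms. It can therefore be too low for these data. In simulated data 28.9% of the usage calls fell on genes without a switch, and the number of usage calls here was 4 without control replicate 1, 7 without control replicate 2, 11 without shMRG replicate 1, 8 without shMRG replicate 2 and 34 among transcripts with at least 50 counts. The adjusted p of XBP1 was 1.0 without shMRG replicate 1 and 1.0 without shMRG replicate 2.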

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

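In simulated data of this size and depth 28.6% of 1.5-fold changes were recovered, and thinning all libraries to the smallest total called 399 genes. MORF4L1 fell under every alternative, past the threshold except on the TPM scale (-1.77 with 1 added, -1.78 with 0.1 added, -1.77 without a filter), and lay between -2.20 and -1.63 with a library left out. The number of genes changed, 363 as reported, was 366 with DESeq2 size factors, 353 without a filter, 382 at a mean of 5 CPM, 381 with voom, 355 among protein-coding genes and 274 with library totals. It was 643 with DESeq2, 61 with the length offset, 5 on log2(TPM + 1), 7 on log2(TPM + 0.1), 0 with limma on log2(TPM + 1) without a filter (2123 at an unadjusted p under 0.05) and 786 with the replicate block, and the cause was not tested. The samples share only a replicate number (correlation of same-numbered deviations 0.0776). A stricter threshold of 0.01 left 51 genes and glmTreat 184. With a library left out it lay between 53 (without control replicate 2) and 2317 (without shMRG replicate 1), the lone sample being assumed to vary like the others.

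The 12 list calls and the 3 senescence list calls became 0 and 0 with an estimated correlation and 0 and 0 with fry. Both allow for genes that vary together, but both also rest on 2 residual degrees of freedom here. A call lost with either therefore does not single out correlation between genes. For the histone list the estimated correlation was 0.0260, near the preset 0.01. Its unadjusted camera p was still 0.0272, against 4.36e-11 with the preset. The adjusted p of the G1/S list was 0.831 with an estimated correlation and 0.301 with fry, that of the G2/M list 0.858 and 0.445, and that of the genes lowered in senescent cells 0.844 and 0.320. DESeq2 itself was not applied to lists.

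The cause was not tested for the following. The secretory factors passed the threshold with library totals (0.0498), the length offset (0.0211), voom (0.0364), 1 added to TPM (0.0140), 0.1 added (0.0172) and protein-coding genes (0.0483), and lay between 0.00347 and 0.866 with a library left out. Direction also turned for lists, of which the interferon list alone was called as reported. For the CDK inhibitors it did so without a filter (0.985), with the block (0.836), without control replicate 2 (0.764) and without shMRG replicate 1 (0.803), with values between 0.736 and 0.938 with a library left out. For the matrix list it did so with library totals (0.955), a mean of 5 CPM (0.991), the length offset (0.949), voom (0.964), 1 added to TPM (0.863), 0.1 added (0.890) and without shMRG replicate 1 (0.232), with values up to 0.936 without control replicate 1. For the SIN3-HDAC list it did so with the length offset (0.930), 1 added to TPM (0.863), 0.1 added (0.890) and unfiltered TPM (0.957). The neuronal list turned without control replicate 1 (0.922), without shMRG replicate 2 (0.696) and with fry (0.643), and lay between 0.195 and 0.922 with a library left out. The AP-1 list turned without control replicate 1 (0.880) and without shMRG replicate 2 (0.162; range 0.121 to 0.880), and the respiratory chain without control replicate 1 (0.292; range 0.151 to 0.967). The hypoxia list turned without shMRG replicate 1 (0.862; range 0.151 to 0.862), as did the fibroblast markers (0.232; range 0.0141 to 0.761). The interferon list, called as lower, turned without shMRG replicate 2 (0.0438) and lay between 4.76e-16 and 0.0561 with a library left out.

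The log2 fold change of CXCL8, not called, lay between -0.16 (without shMRG replicate 1) and 1.14. Those of CDKN1A and HMGB2 lay between -0.10 and 0.17 and between -1.24 and 0.0115, turning without shMRG replicate 2. For the 47 called named genes besides MORF4L1, 521 of 751 values under alternatives stayed past the threshold, 230 did not and 0 turned direction. All 363 called genes had groups that did not overlap, so their direction could hardly turn on these libraries. The 0 is therefore no separate support.

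Transcript usage calls, 119 as reported, were 84 with the Simes p (71 shared), 34 at 50 counts (23 shared), 23 at 10% of the gene (19 shared), 1 with the block and between 4 and 11 with a library left out, of which 1 or 2 were shared, and the cause was not tested.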

Other observations

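Several genes that TGF-beta signalling is known to raise passed the gene test, and they were singled out only after their values were seen, so they are no test of that pathway. BHLHE40, CDKN2B, EDN1, NEDD9, PMEPA1, SKIL, TGFB2 and TGFBR2 rose, 8 of 24 tested genes gathered in this way. The feedback inhibitors PMEPA1 and SKIL rose by 1.03 and 0.80 on the log2 scale (edgeR adjusted p = 0.0355 and 0.018), and the receptor TGFBR2 by 0.80 (adjusted p = 0.0457). Of 21 NRF2 targets and ferritin genes, gathered in the same way, FTL, SLC7A11 and SQSTM1 rose.

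Of 14 genes of simple keratins and desmosomes, also gathered after their values were seen, KRT8, KRT18, DSP and PKP2 rose. KRT18, a keratin of simple epithelia, rose by 1.32 and the desmosomal PKP2 by 1.56 on the log2 scale (edgeR adjusted p = 0.0121 and 0.00857). In control KRT8 measured 20 ± 0.0629, KRT18 28.0 ± 1.08, DSP 345 ± 4.90, DSG2 230 ± 11.8 and DSC3 117 ± 12.3 CPM, so epithelial genes outside the fixed list of keratinocyte and epithelial markers were expressed. Of 17 genes of MHC class I antigen presentation, gathered likewise, 1 rose and 2 fell. The paralog pair RGPD6 and RGPD5 went from 9.54 to 28.4 CPM and from 32.3 to 14.2 CPM, and together from 41.8 ± 0.841 to 42.6 ± 1.14 CPM.

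Below, leaving out shMRG replicate 2 and estimating the correlation were planned, and the other tests, on the markers, the thinned libraries and the XBP1 isoforms, were chosen only after the results were seen. The first pattern is the abundance of fibroblast transcripts in libraries labelled HEK293T, with COL1A1 at 6796 TPM and COL1A2 at 4248 TPM in control. The knockdown did not switch these genes on, since 10 of 10 markers exceeded 10 TPM in both control libraries. RNA from another cell type than the label names is a candidate explanation, since 2 of 16 neuronal genes of HEK293 cells exceeded 10 TPM in all libraries. The marker list shares 0 genes with the list of matrix and mesenchymal genes. A minor share of fibroblast RNA mixed into HEK293T RNA cannot be told apart from it, because the neuronal median of 0.609 TPM in control has no pure HEK293T profile beside it.

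The second pattern is the fall of G1/S genes. The library with the larger fall, shMRG replicate 2, is not its whole cause, since the median log2 fold change without it was -0.59. That value rests on shMRG replicate 1 alone. Read depth is not either, since the median was -0.91 after all libraries were thinned to the smallest total. Cultures that differed in growth for another reason than the shRNA cannot be told apart from an effect of the knockdown, because 2 libraries per group carry both (adjusted p = 0.831 with an estimated correlation).

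The third pattern is the form of XBP1 that lacks the 26-base intron removed by IRE1 in the unfolded protein response. The 2 annotated isoforms without it held 6.76% ± 0.583 of XBP1 counts in control and 19.7% ± 5.72 in shMRG (11.6% ± 0.828 and 23.8% ± 6.18 of its TPM). Of these, XBP1-202 held 6.76% ± 0.583 of counts in control and 6.59% ± 1.32 in shMRG. The rise lay in XBP1-207 alone, with 0 counts in control and 13.1% ± 4.39 in shMRG. Reads that moved only between the 2 isoforms without the intron would leave their share of counts unchanged, and the lower shMRG share of counts was 2.18 times the higher control share. That ratio rests on the same XBP1-207 counts as the usage call, so it is no separate support for that call. Assignment of reads by the ends of XBP1-201 and XBP1-207 stays open, because the isoforms differ there by 30 bases besides the intron and reads over the junction were not available. Activation of the unfolded protein response may contribute and stays open too, since the ER list was higher with the preset but not with the estimated correlation (adjusted p = 0.831 with an estimated correlation).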
